A study of Mus musculus with 8 samples.

How the data were processed

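The deposited table lists 2403 small RNA features (microRNAs, small nucleolar and nuclear RNAs, genomic and mitochondrial transfer RNAs, piRNAs, ribosomal RNAs and others) in 8 samples. Its values are the authors' score, per the labels a normalized read count, and are whole numbers. In each library the low values fall on multiples of 1 step (0.826 to 1.138, found on a grid from 0.7 to 1.4 over values up to 60), as 1 scaling factor per library would give, except that in WT normoxia number 1 the step of 0.992 could not be told from a step of 1. Reads assigned were taken as the total over the step. Totals ran from 8618630 (KO normoxia number 1) to 12167438 (WT hypoxia number 2), so a count of 0 allows shares of 2.47e-05% to 3.48e-05% (3 counts over the total). Upstream trimming, alignment, the reference build, the treatment of reads that match several features and the normalization method are not given in the sources used here. RNA was isolated with a miRNeasy kit and the libraries were made with a NEBNext small RNA set for SOLiD, per the labels.

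Features were tested when they held at least 10 in at least 2 of the 8 libraries, which left 1540 (579 microRNAs, 413 genomic transfer RNAs, 376 small nucleolar RNAs, 79 piRNAs, 41 small nuclear RNAs, 22 mitochondrial transfer RNAs, 14 miscellaneous RNAs, 13 ribosomal RNAs and 3 other transfer RNAs). limma (with an intensity trend) was fitted to log2(value + 1) with 4 group means over the 8 libraries, 4 residual degrees of freedom and 5.64 prior degrees of freedom. Contrasts were hypoxia minus normoxia in WT and in KO, KO minus WT in normoxia and in hypoxia, the interaction (KO change minus WT change), and the mean of the hypoxia and of the genotype contrasts. P-values were adjusted by Benjamini-Hochberg over the features tested, with a threshold of 0.05. Means are given ± SD over the 2 libraries of a group, and differences with the standard error of the limma fit. The replicate numbers were not treated as pairs, a choice settled after the calls with and without the number as a block had been seen. Deviations by number were correlated between groups (r from 0.15 to 0.55), so this structure stays in the residual spread of the main fit.

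Gene lists were tested by camera with a preset correlation of 0.01, adjusted over the lists within a contrast, where at least 3 members were tested. Of 17 lists 16 could be tested. They were microRNAs described as responding to hypoxia (named the hypoxia-induced list below), fibroblast activation, let-7, the miR-17/92 family, miR-34 and the miR-322 and miR-503 cluster. The hypoxia-induced list sets no direction for its members, so its name does not mean that each is induced. Members that respond in opposite directions would offset each other in its median and in camera. Further lists were miR-15/16, miR-30, miR-221 and miR-222, the Hox-embedded microRNAs, the Dlk1-Dio3 domain and the Sfmbt2 cluster. The last were microRNAs typical of epithelial, haematopoietic, muscle, and neural or melanocyte cells. The endothelial list had too few members. The correlation estimated from the data ran from 0.046 (muscle) to 0.72 (miR-34), with 0.57 for Dlk1-Dio3 and 0.30 for the Sfmbt2 cluster. The preset 0.01 lies below all of these, so p-values with it overstate the evidence where members move together. The lists, the contrasts, the filter, the alternative settings and the rule for named features were set before the data were examined. The rule took both arms of miR-210, in each of the 4 pairwise contrasts the 12 risen and 12 fallen features with the largest change past the threshold and with no overlap between the groups (and the 5 with the smallest p where fewer than 5 pass), in the other contrasts the 6 past the threshold with the smallest adjusted p (or the 3 with the smallest p where none passes), up to 4 members of each list with the highest mean, and the 6 most abundant features. miR-16-2-3p, miR-15a-3p, miR-410-5p and miR-345 fall outside this rule and were chosen after their values were seen.

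Alternatives planned were pseudocounts of 8 and 0.5, no filter, a mean of at least 50, TMM factors, quantile normalization, no intensity trend, the replicate number as a block, fitting the groups of a contrast alone, leaving out each library in turn, and for lists an estimated correlation and leaving out members that share a stem with another list. Scaling to the microRNA total, testing microRNAs alone, leaving out KO normoxia number 2 and KO hypoxia number 1 together, and every rerun of the lists other than those with an estimated correlation or without shared stems were chosen after seeing the data. The fit was also run on 20 simulated tables shaped like the comparison of genotypes in hypoxia. In each, 200 of 1540 features were changed 2-fold to 16-fold, and a list of 78 others was moved by 1. The fit called 35.7% of those changed 2-fold, 86.6% at 4-fold, 96.2% at 8-fold and 97.9% at 16-fold, and 0.684% of the unchanged. The adjusted threshold is easier to pass where so many features change, so these rates may be too high for the real comparisons. The moved list of 78 was called in 100% of the tables with either correlation, and an unmoved list in 0%. The simulated features varied independently of each other, so these rates say nothing on lists whose members move together. Shares of feature classes were compared by exact two-sided permutation of 4 libraries against 4. The small nucleolar RNAs of the Dlk1-Dio3 region, the mitochondrial transfer RNAs and a few chosen features were matched by sequence to GENCODE M21 transcripts. Other features without a gene name were not matched. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.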

Results

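Small RNA libraries were sequenced from immortalized mouse skin fibroblasts of wild-type C57BL/6 mice (WT) and of mice with the mir210lox/lox genotype, whose samples are titled KO. Cells of each genotype were kept for 24 h in normoxia (21% O2) or hypoxia (1% O2). The 4 groups held 2 libraries each, numbered 1 and 2, so 8 libraries were compared. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The normalized read counts of a library summed to 8618630 to 12167438, and 1 read was worth 0.826 to 1.138 units, which gives 7573489 to 13482280 reads assigned to the 2403 listed features. MicroRNAs took 73.0% to 82.0% of each total. Replicates correlated with r between 0.974 and 0.984 over the log2 values of 1540 features, and 8.70% to 15.8% of features differed more than 2-fold between the libraries of a group.

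The most abundant features were microRNAs typical of fibroblasts and other mesenchymal cells, together with a ribosomal RNA. miR-21-5p alone took 27.5% of all normalized counts, miR-22-3p 9.12%, miR-125b-5p 3.68%, miR-143-3p 3.11%, the ribosomal RNA feature ENSMUST00000104719 2.46% and miR-24-3p 2.07%. miR-21-5p held 2903929 ± 124490 in WT normoxia, 3077200 ± 239040 in WT hypoxia, 2625844 ± 505410 in KO normoxia and 2830300 ± 181810 in KO hypoxia (mean ± SD, n = 2). None of these 6 features passed the test in any comparison. Ribosomal RNA took 5.76% of the KO hypoxia number 1 library and 1.69% to 2.88% of each of the others. Its mean share was 3.36% in KO against 1.90% in WT (exact two-sided permutation test, 4 libraries against 4, p = 0.0286, adjusted p = 0.419 over 22 tests of feature classes). None of the 22 class tests passed, and 0.0286 is the smallest p this design allows.

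miR-210, the microRNA named in the genotype and a well known target of hypoxia-inducible factor, set the 2 genotypes apart in every library. The guide arm miR-210-3p (ACTGTGCGTGTGACAGCGGCTGAT in the file, chromosome 7, 148407305 to 148407328) held 4786 and 8676 in the WT normoxia libraries and 36738 and 39011 in the WT hypoxia libraries. In the KO libraries it held 23 and 14 in normoxia and 10 and 32 in hypoxia. The other arm, miR-210-5p (CAGCCACTGCCCACCGCACACTGC, 148407343 to 148407366), held 11 and 21 in WT normoxia, 163 and 246 in WT hypoxia, 1 and 1 in KO normoxia, and 0 and 1 in KO hypoxia. The WT and KO titles and the measured miR-210 thus go the same way in all 8 libraries. The oxygen labels do so in the WT libraries, and miR-210 cannot check them in the KO libraries. The genotype label mir210lox/lox does not itself state a deletion, so the name KO rests on the titles and on these counts. miR-210-3p made up 0.0488% of the WT normoxia number 1 library (95% exact binomial interval 0.0474% to 0.0502%) and 0.370% of the WT hypoxia number 1 library (0.366% to 0.374%). The 0 of miR-210-5p in KO hypoxia number 1 allows a share of up to 3.11e-05% (3 counts over the library's total). These intervals and limits treat the normalized values as reads and cover counting error only. The coordinates are the file's own. They run past the last gene of chromosome 7 in GRCm38, so they belong to another build, which is not given in the sources used here. Whether another gene overlaps Mir210 was not tested.

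**Figure D1:**
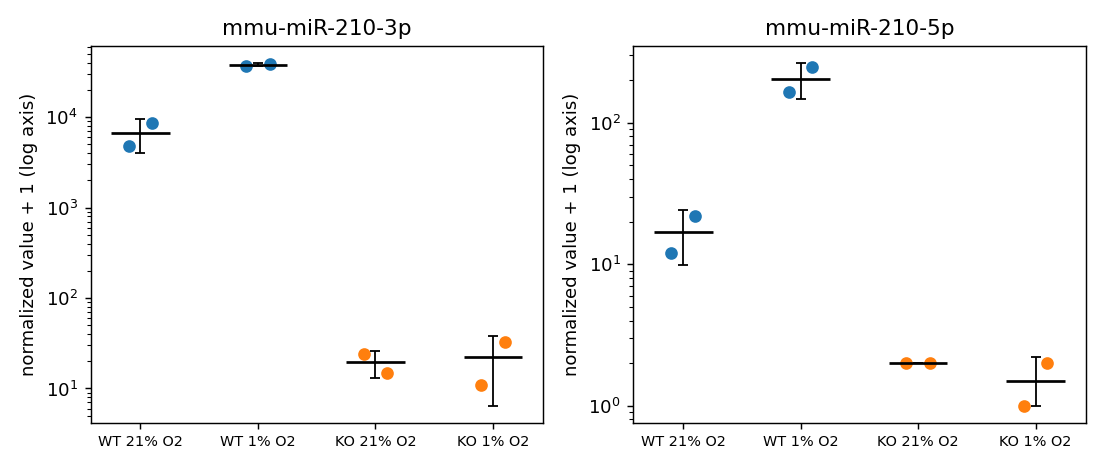
Normalized read count + 1 of miR-210-3p and miR-210-5p on a log axis, by group. Points are the 2 libraries, lines their mean and bars ± 1 SD, stopped below at a count of 0, and miR-210-3p lies at 4786 or above in the 4 WT libraries and at 32 or below in the 4 KO libraries.

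Hypoxia in WT cells was accompanied by higher miR-210 on both arms. miR-210-3p went from 6731 ± 2751 to 37874 ± 1607 (SD, n = 2), a log2 change of 2.55 (SE 0.50), and miR-210-5p from 16 ± 7.07 to 204.5 ± 58.7, a log2 change of 3.63 (SE 0.60). Within number 1 and number 2 the differences were 2.94 and 2.17 for miR-210-3p and 3.77 and 3.49 for miR-210-5p. Adjusted over the 2 arms alone, limma gave adjusted p = 5.47e-04 and 3.06e-04, and over all 1540 features tested adjusted p = 0.332 and 0.235. Next by p-value came 3 asparagine transfer RNA features, none of them past the threshold. chr3.tRNA294-AsnGTT held 959 ± 266 in normoxia and 3391 ± 1283 in hypoxia (log2 change 1.80, SE 0.40, adjusted p = 0.332). The nearby copy chr3.tRNA750-AsnGTT gave almost identical values (1.80, SE 0.40, adjusted p = 0.332), and chr1.tRNA814-AsnGTT went from 119 ± 28.3 to 365 ± 129 (1.58, SE 0.35, adjusted p = 0.332).

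No feature passed the test between WT hypoxia and WT normoxia (limma, 0 of 1540 features at adjusted p under 0.05), and 20 had an unadjusted p under 0.05, 17 of them higher, where 77 are given by chance. None of the 16 microRNA lists tested was called, and 0 members of any list passed adjusted over the list alone. The count of 0 lists became 2 without WT normoxia number 1 (both lower), 3 without WT normoxia number 2 or WT hypoxia number 1 (2 higher, 1 lower) and 3 without WT hypoxia number 2 (all lower), all with the preset correlation. The microRNAs described as responding to hypoxia, other than miR-210, had a median log2 change of 0.01 over 35 members (18 higher, 17 lower). Camera gave adjusted p = 0.874, and adjusted p = 0.933 with an estimated correlation. Their most abundant members were miR-24-3p (−0.09, SE 0.42), miR-23b-3p (0.21), miR-23a-3p (0.26) and miR-199a-3p (0.50). The let-7 family had the smallest list p, with a median of −0.15 and 17 of 21 members lower (adjusted p = 0.0992, adjusted p = 0.933 with an estimated correlation). Medians of the lists that mark other cell types were −0.32 for epithelial, 0.28 for haematopoietic, 0.07 for muscle and −0.01 for neural and melanocyte microRNAs, and none was called. The endothelial list, with 2 members, was too small to test, and its miR-126-3p held 129.5 ± 14.8 in WT normoxia and 87.5 ± 16.3 in KO normoxia. Of the remaining lists, medians were −0.14 for the miR-17/92 family, −0.10 for miR-15/16 (mean 0.03), −0.07 for fibroblast activation, 0.06 for miR-34, 0.19 for the miR-322 and miR-503 cluster, 0.05 for miR-30, 0.04 for miR-221 and miR-222, −0.20 for the Hox-embedded microRNAs, 0.13 for Dlk1-Dio3 and 0.16 for the Sfmbt2 cluster. The count of 0 depended on the fit. With a pseudocount of 8 or a filter on a mean of at least 50 it was 1 (miR-210-5p, whose adjusted p ranged from 0.00641 to 0.993 over the alternatives), and with the replicate number as a block it was 8, namely both miR-210 arms and 6 asparagine transfer RNA features.

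Hypoxia in KO cells left miR-210 near its floor, with a log2 change of 0.01 (SE 0.50) for miR-210-3p and −0.50 (SE 0.60) for miR-210-5p. The sign for miR-210-3p turns under other scalings (−0.026 with TMM factors, −0.11 after quantile normalization and −0.14 on the microRNA total), and within number 1 and number 2 it was −1.13 and 1.14. The smallest p-values belonged to FR231715, a small nuclear RNA whose sequence matches the gene Gm23907 (68.5 ± 2.12 in normoxia, 218 ± 52.3 in hypoxia, log2 change 1.64, SE 0.35), and to ENSMUST00000082420, the mitochondrial glutamate transfer RNA mt-Te (1478 ± 448 against 569.5 ± 85.6, −1.35, SE 0.30). They were followed by miR-467a-5p (2400 ± 96.2 against 5787.5 ± 330, 1.27, SE 0.31), miR-669b-3p (1.5 ± 0.707 against 10.5 ± 2.12, 2.22, SE 0.55) and miR-467b-5p (240 ± 9.90 against 578.5 ± 33.2, 1.27, SE 0.32), which belong to the large microRNA cluster in an intron of Sfmbt2 on chromosome 2. The adjusted p of each of the 5 was 0.804. miR-467a-5p and miR-467b-5p are not separate measurements, since their values stood at a ratio of 9.99 to 10.01 in every library.

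No feature passed between KO hypoxia and KO normoxia (limma, 0 of 1540), and 83 had an unadjusted p under 0.05, 38 higher and 45 lower. With camera's preset correlation 5 lists were called, all higher. The Sfmbt2 cluster had a median log2 change of 0.61 with 55 of 57 members higher (adjusted p = 2.05e-14, adjusted p = 0.644 with an estimated correlation, 0 members past adjusted over the list alone). Within number 1 its median was 0.18 and within number 2 it was 1.03. The miR-15/16 family, which restrains the cell cycle, had a median of 0.56 with 8 of 8 higher (adjusted p = 6.12e-05, adjusted p = 0.644 with an estimated correlation), and miR-16-2-3p (1.27, SE 0.38) and miR-15a-3p (0.93, SE 0.28) passed adjusted over the list alone. The growth-promoting miR-17/92 family had a median of 0.48 with 17 of 20 higher (adjusted p = 1.14e-04, adjusted p = 0.644 with an estimated correlation), among them miR-106b-5p at 0.75 (SE 0.25) and miR-92a-3p at 0.62 (SE 0.43). Its median was 0.68 within number 1 (20 of 20 higher) and −0.0016 within number 2 (10 of 20 higher), and those of miR-15/16 were 0.74 and 0.58. The hypoxia-induced list had a median of 0.27 with 30 of 35 higher (adjusted p = 0.00395, adjusted p = 0.644 with an estimated correlation) and the imprinted Dlk1-Dio3 list 0.27 with 65 of 78 higher (adjusted p = 9.18e-04, adjusted p = 0.723 with an estimated correlation), both with 0 members past adjusted over the list alone. Within numbers their medians were 0.12 and 0.33, and 0.15 and 0.35. Among microRNAs only, whose median here was 0.24, the calls of the Sfmbt2 cluster (adjusted p = 1.01e-07) and of miR-15/16 (adjusted p = 0.0102) held with the preset correlation and were lost with an estimated correlation (adjusted p = 1.00 for both), and those of the other 3 were lost. Of the lists that mark other cell types, none called, muscle had a median of 0.86 (2 of 3 higher), neural and melanocyte 0.49 (3 of 3 higher), haematopoietic −0.27 (4 of 5 lower) and epithelial 0.22 (3 of 5 higher). Without KO normoxia number 2 the Sfmbt2 median was 0.28, and without KO hypoxia number 1 the miR-17/92 call was lost (0.19, against 0.80 without KO hypoxia number 2). The count of 2 for miR-15/16 was 0 without either WT hypoxia library, either KO normoxia library or KO hypoxia number 1, and without both KO normoxia number 2 and KO hypoxia number 1 the call of this list was lost (0.37). The hypoxia-induced list was lost without KO normoxia number 1 (0.19) or KO hypoxia number 2 (0.11), the Dlk1-Dio3 list without KO hypoxia number 2 (0.25), and without KO hypoxia number 1 these medians were 0.50 and 0.41.

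The response to hypoxia was compared between genotypes by the interaction, the KO change minus the WT change. It was −2.55 (SE 0.71) for miR-210-3p and −4.13 (SE 0.86) for miR-210-5p, with adjusted p = 0.00537 and 0.00154 over the 2 arms alone and 1.00 and 0.917 over all features (limma). By p-value over all features, miR-210-5p was followed by FR231715 at 2.22 (SE 0.49, adjusted p = 0.917) and miR-467a-5p at 1.66 (SE 0.44, adjusted p = 1.00). Both came ahead of miR-210-3p. Features past the threshold numbered 0 of 1540 (limma), with 37 at an unadjusted p under 0.05. With the preset correlation 6 lists were called, each with the more positive change in KO: the miR-17/92 family (median 0.66, adjusted p = 4.63e-06), miR-15/16 (0.60, adjusted p = 5.07e-04), the Sfmbt2 cluster (0.44, adjusted p = 7.91e-08), let-7 (0.38, adjusted p = 0.00255), the hypoxia-induced list (0.25, adjusted p = 0.0384) and Dlk1-Dio3 (0.19, adjusted p = 0.0425). With an estimated correlation the adjusted p of these lists lay between 0.605 and 0.770, and 0 members of any list passed adjusted over the list alone. The hypoxia-induced list lost its call without WT normoxia number 2 (0.02), WT hypoxia number 1 (−0.0086), KO normoxia number 1 (0.17) or KO hypoxia number 2 (0.10). Dlk1-Dio3 lost it without WT normoxia number 2 (−0.19), WT hypoxia number 1 (−0.28), either KO normoxia library (0.22 and 0.12) or KO hypoxia number 2 (0.10). With the replicate number as a block 5 of the 6 calls held, and that of Dlk1-Dio3 was lost. The let-7 call was lost without WT normoxia number 2 (0.32), WT hypoxia number 1 (0.29) or KO normoxia number 2 (0.27). Without KO hypoxia number 1 the miR-17/92 and miR-15/16 medians were 0.40 and 0.31, and without WT normoxia number 1 the miR-17/92 median was 0.44. The Sfmbt2 median was 0.14 without KO normoxia number 2, 0.26 without WT hypoxia number 1 and 0.70 without KO normoxia number 1. Among microRNAs alone miR-17/92 (adjusted p = 0.00737), the Sfmbt2 cluster (adjusted p = 0.00737) and miR-15/16 (adjusted p = 0.0305) kept their calls with the preset correlation, and the haematopoietic list, not called against all features, was called against these (median −0.33, adjusted p = 0.0191). All 4 were lost there with an estimated correlation (adjusted p = 0.930). Without KO normoxia number 2 and KO hypoxia number 1 together the calls of miR-17/92 (0.28), miR-15/16 (0.30), let-7 (0.28) and Dlk1-Dio3 (0.21) were lost, and 2 of the 6 calls held. Across 1538 features the hypoxia changes in WT and KO correlated with r = 0.109, where features are not independent replicates.

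In normoxia, KO cells differed from WT cells in 1 feature, miR-210-3p, which fell by 8.41 on the log2 scale (SE 0.50, limma adjusted p = 3.06e-05), with differences of −7.64 and −9.18 within number 1 and number 2. Its summed counts were 364 times higher in WT (95% exact interval 264 to 517, counting error only). miR-210-5p, with 32 counts in WT and 2 in KO (ratio 16, interval 4.08 to 138), had a log2 difference of −3.02 (SE 0.60) that did not pass over all features (adjusted p = 0.231) and passed adjusted over the 2 arms alone (adjusted p = 6.03e-04). With counts this low the difference depends on the pseudocount, and it was −1.38 with 8. The count of 1 was 2 without an intensity trend and 2 without WT hypoxia number 2. Besides miR-210-5p, the smallest p-values not past the threshold, at adjusted p = 0.231 each, were those of miR-501-3p (46.5 ± 4.95 in WT, 229 ± 5.66 in KO, log2 difference 2.28, SE 0.44), the small nucleolar RNA FR014374 from the Dlk1-Dio3 region of chromosome 12 (121.5 ± 4.95 against 383 ± 110, 1.62, SE 0.33) and miR-669b-3p (14.5 ± 2.12 against 1.5 ± 0.707, −2.65, SE 0.55).

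In all, 207 features had an unadjusted p under 0.05 in this comparison, 133 higher and 74 lower in KO, where 77 are given by chance. Without WT normoxia number 1 this excess over chance was gone. By camera with the preset correlation 1 list was higher and 8 were lower in KO normoxia. The microRNAs of the imprinted Dlk1-Dio3 domain, expressed from the maternal chromosome, had a median log2 difference of 0.96 with 75 of 78 higher (adjusted p = 1.07e-21, adjusted p = 0.408 with an estimated correlation), 33 at an unadjusted p under 0.05 and 0 past adjusted over the list alone (13 without either WT hypoxia library). miR-127-3p held 5316.5 ± 2334 in WT and 10832 ± 2402 in KO (1.08, SE 0.54), and miR-379-5p 2434 ± 979 and 4590.5 ± 549 (0.97, SE 0.40). Within number 1 the list's median was 1.39 and within number 2 it was 0.51. The Sfmbt2 cluster had a median of −0.89 with 55 of 57 lower (adjusted p = 1.54e-19, adjusted p = 0.408 with an estimated correlation, within numbers −0.58 and −1.12). Adjusted over the list alone 3 members passed, miR-669b-3p, miR-467a-5p (−1.46, SE 0.31) and miR-467b-5p (−1.45, SE 0.32), a count that was 34 without KO normoxia number 1 and 0 without either WT normoxia library or KO normoxia number 2. The let-7 family (median −0.55, 19 of 21 lower, adjusted p = 4.01e-05), miR-17/92 (−0.65, 19 of 20 lower, adjusted p = 2.19e-05) and miR-15/16 (−0.64, 8 of 8 lower, adjusted p = 4.58e-04) had adjusted p = 0.408 each with an estimated correlation, as had the hypoxia-induced list (−0.35, 29 of 35 lower, adjusted p = 0.00633). Their abundant members included let-7f-5p (−0.54, SE 0.31), miR-19b-3p (−0.53, SE 0.28) and miR-16-5p (−0.74, SE 0.30). The p53-responsive miR-34 family (−0.59, adjusted p = 0.0226, adjusted p = 0.453 with an estimated correlation), the miR-322 and miR-503 cluster (−0.73, adjusted p = 0.0226, adjusted p = 0.561 with an estimated correlation) and the fibroblast activation list (−0.20, adjusted p = 0.0443, adjusted p = 0.561 with an estimated correlation) were the other 3. In each of these 7 lists 0 members passed adjusted over the list alone. Medians within number 1 and number 2 were −0.24 and −0.82 for let-7, −0.75 and −0.41 for miR-17/92, −0.31 and −0.82 for miR-15/16, −0.14 and −0.42 for the hypoxia-induced list, −0.41 and −0.69 for miR-34, −0.52 and −1.09 for the miR-322 and miR-503 cluster, and −0.14 and −0.30 for fibroblast activation. Not called were miR-30 (−0.23), miR-221 and miR-222 (0.18), the Hox-embedded microRNAs (−0.25) and the epithelial (−0.13), haematopoietic (−0.54), muscle (−0.87) and neural and melanocyte (−0.63) lists.

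All microRNAs together had a median of −0.28 in this comparison, and among microRNAs alone 5 of the 9 calls held, those of Dlk1-Dio3, the Sfmbt2 cluster, let-7, miR-17/92 and miR-15/16. All 5 were lost there with an estimated correlation (adjusted p = 0.448 and 0.765 for Dlk1-Dio3 and the Sfmbt2 cluster and 0.905 for the others). Without WT normoxia number 1 the Dlk1-Dio3 median was 0.56 and the miR-322 and miR-503 median −1.14, and without KO normoxia number 2, which stood apart on the third principal component of the microRNAs, the Sfmbt2 and let-7 medians were −0.50 and −0.36. Leaving out WT normoxia number 2 or KO normoxia number 1 ended the calls of the hypoxia-induced (−0.21 and −0.20), miR-34 (−0.48 and −0.56), miR-322 and miR-503 (−0.20 and −0.36) and fibroblast activation lists (0.023 and −0.12), whose median also turned on the microRNA total (0.035) and was −0.47 without WT normoxia number 1 and −0.39 without KO normoxia number 2. The hypoxia-induced median was −0.62 without WT normoxia number 1. The KO normoxia libraries also entered the hypoxia comparison in KO, so the opposite signs of the lists there share their chance deviations.

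**Figure D2:**
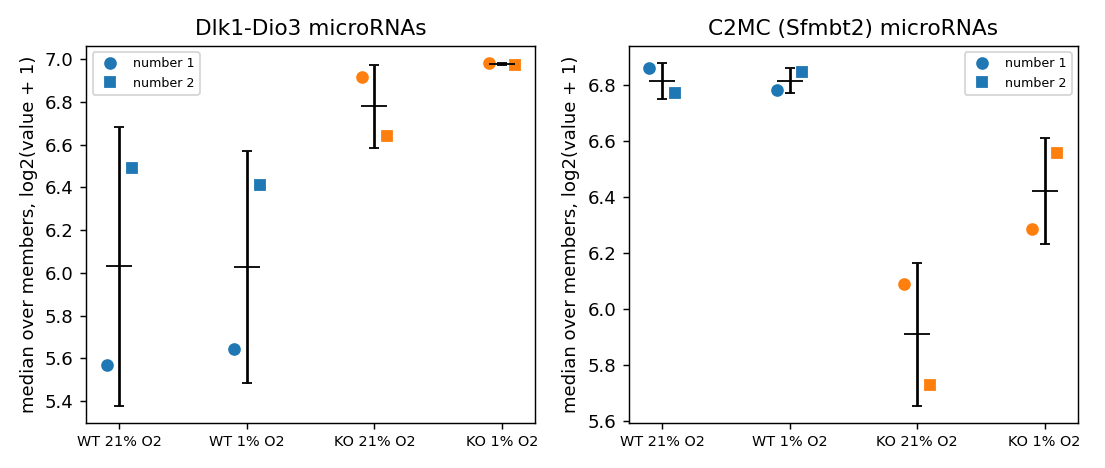
Median log2(normalized read count + 1) of the Dlk1-Dio3 list (78 microRNAs) and of the Sfmbt2 cluster (57 microRNAs) in each of the 8 libraries, with circles for number 1, squares for number 2, and group means ± 1 SD. The Dlk1-Dio3 medians of the KO libraries, from 6.64, lie above those of the WT libraries, up to 6.49, and the Sfmbt2 medians of the KO libraries, up to 6.55, below those of the WT libraries, from 6.77.

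In hypoxia, KO cells differed from WT cells in 2 features, both arms of miR-210. miR-210-3p fell by 10.96 (SE 0.50, limma adjusted p = 2.54e-06) and miR-210-5p fell by 7.15 (SE 0.60, adjusted p = 3.63e-04), lower in both KO libraries than in both WT libraries. The size for miR-210-5p depends on the pseudocount, at −4.62 with 8 and −7.86 with 0.5. In summed counts WT held 1804 times as much miR-210-3p (1334 to 2503) and 409 times as much miR-210-5p (73.0 to 16190, from a single KO count). Of the features that did not pass, the smallest p-values were those of miR-540-5p (131.5 ± 20.5 in WT, 506.5 ± 186 in KO, log2 difference 1.90, SE 0.35, adjusted p = 0.189) and of 2 overlapping small nucleolar RNA features whose sequences match AF357341, FR310934 (1.45, SE 0.33, adjusted p = 0.461) and FR325285 (1.46, SE 0.33, adjusted p = 0.461). All 3 lie in the Dlk1-Dio3 region.

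The Dlk1-Dio3 microRNAs were again higher in KO, with a median of 1.21 and 77 of 78 higher (camera adjusted p = 4.81e-45, adjusted p = 0.650 with an estimated correlation). Of these 56 had an unadjusted p under 0.05, and 1, miR-540-5p, passed adjusted over the list alone. miR-127-3p went from 5772 ± 4422 in WT to 11952 ± 3285 in KO (1.27, SE 0.54), and miR-337-3p from 1434 ± 675 to 2864 ± 87.7 (1.08, SE 0.37). Within number 1 the median was 1.61 and within number 2 it was 0.77. The Sfmbt2 cluster had a median of −0.41 with 51 of 57 lower (adjusted p = 7.45e-06, adjusted p = 0.989 with an estimated correlation), and the miR-34 family one of −0.45 with 6 of 6 lower (adjusted p = 0.0296, adjusted p = 0.989 with an estimated correlation). In both, 0 members passed adjusted over the list alone, and medians within numbers were −0.32 and −0.39, and −0.70 and −0.24. Among microRNAs alone the miR-34 call was lost (adjusted p = 0.0682), and those of Dlk1-Dio3 and the Sfmbt2 cluster held with the preset correlation and were lost with an estimated correlation (adjusted p = 0.437 and 0.945). The haematopoietic list was lower without being called (median −0.88, adjusted p = 0.0567), with miR-451 at 2232.5 ± 1066 in WT and 1132 ± 484 in KO. Without WT hypoxia number 1 the Dlk1-Dio3 median was 0.72, and without WT hypoxia number 2 the Sfmbt2 median was −0.24. The miR-34 call was lost without WT hypoxia number 2 (−0.32) or KO hypoxia number 1 (−0.08), the library with most ribosomal RNA, and stood at −0.83 without KO hypoxia number 2. The count of 1 Dlk1-Dio3 member was 49 with TMM factors, 61 on the microRNA total, 64 with the replicate block, 51 without WT hypoxia number 2, and 0 without WT normoxia number 1 or 2, WT hypoxia number 1 or KO hypoxia number 1. In this comparison 139 of 1540 features had an unadjusted p under 0.05, 110 higher and 29 lower, where 77 are given by chance. This excess was gone without WT hypoxia number 1 or KO hypoxia number 1.

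Averaged over both oxygen levels, 2 features differed between the genotypes, miR-210-3p (−9.68, SE 0.36, limma adjusted p = 3.05e-07) and miR-210-5p (−5.09, SE 0.43, adjusted p = 3.44e-04), and 274 had an unadjusted p under 0.05, 190 higher and 84 lower in KO. Adjusted over the list alone, 69 of the 78 Dlk1-Dio3 microRNAs rose in KO, by 0.67 to 1.65 on the log2 scale, and 0 passed over all features (with the replicate block, 41 did). The list's median was 1.08, with 77 of 78 higher (camera adjusted p = 1.69e-40, adjusted p = 0.471 with an estimated correlation). miR-410-5p was the exception (−0.64). The count of 69 depended on single libraries. It was 0 without WT normoxia number 1, 8 without WT hypoxia number 1, 43 without KO normoxia number 1, 42 without KO hypoxia number 2 and 2 without both KO normoxia number 2 and KO hypoxia number 1. The Sfmbt2 cluster had a median of −0.63 with 56 of 57 lower (adjusted p = 1.16e-16, adjusted p = 0.471 with an estimated correlation) and 0 members past adjusted over the list alone. Also lower were let-7 (−0.37, adjusted p = 0.00108), miR-34 (−0.51, adjusted p = 0.00964), miR-17/92 (−0.28, adjusted p = 0.0108), miR-15/16 (−0.28, adjusted p = 0.0253), the miR-322 and miR-503 cluster (−0.59, adjusted p = 0.0277) and the hypoxia-induced list (−0.21, adjusted p = 0.0416). The adjusted p of these 6 with an estimated correlation lay between 0.471 and 0.534, and 0 of their members passed adjusted over the list alone. The lists that mark other cell types were lower too without being called, at −0.85 for muscle (3 of 3 lower), −0.43 for haematopoietic (5 of 5 lower), −0.35 for neural and melanocyte (3 of 3 lower) and −0.13 for epithelial (4 of 5 lower). Among microRNAs alone none of these 6 was called (adjusted p from 0.0917, for let-7), while Dlk1-Dio3 and the Sfmbt2 cluster were, both lost with an estimated correlation (adjusted p = 0.265 and 0.796). The call of the hypoxia-induced list was also lost without members shared with another list (median −0.20). Of the 6, let-7 kept its call without each library in turn and miR-34 lost it without KO hypoxia number 1 (−0.32). Without WT normoxia number 2 or WT hypoxia number 2 the calls of miR-15/16 (−0.23 and −0.21), miR-322 and miR-503 (−0.19 and −0.23) and the hypoxia-induced list (−0.13 and −0.08) were lost. The same held without KO normoxia number 1 or KO hypoxia number 1 for miR-322 and miR-503 (−0.37 and −0.30) and the hypoxia-induced list (−0.13 and −0.09), and without KO normoxia number 2 or KO hypoxia number 2 for miR-15/16 (−0.30 and −0.21). miR-17/92 lost its call without WT normoxia number 1 (−0.21), WT hypoxia number 1 (−0.22) or KO hypoxia number 2 (−0.11), and was −0.47 without KO hypoxia number 1. miR-322 and miR-503 was −0.98 and −0.91 without WT normoxia number 1 and WT hypoxia number 1, and the hypoxia-induced median was −0.34 without WT hypoxia number 1. The number of features past the threshold depended on the scaling, the block and single libraries. Against 0 higher and 2 lower as deposited and the same after quantile normalization, 13 were higher and 3 lower with TMM factors, 81 and 4 on the microRNA total, 78 and 13 with the replicate block, 25 and 4 without WT hypoxia number 2, and 1 and 3 without KO hypoxia number 2. Scaling to the microRNA total moved the median of all features from −0.06 to 0.13. Of the 8 list calls, 6 held after quantile normalization and 7 on the microRNA total. Across 1538 features the genotype differences in normoxia and hypoxia correlated with r = 0.427.

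Averaged over both genotypes, hypoxia gave 0 of 1540 features past the threshold (limma) and 55 at an unadjusted p under 0.05. The smallest p-values were those of mt-Te (ENSMUST00000082420, −0.94, SE 0.21), chr3.tRNA750-AsnGTT (1.13, SE 0.28) and chr3.tRNA294-AsnGTT (1.13, SE 0.28), with adjusted p = 0.975 each. With the replicate number as a block 3 features passed, all of them AsnGTT transfer RNAs. With the preset correlation 4 lists were higher, the Sfmbt2 cluster (median 0.35, adjusted p = 2.84e-11), miR-15/16 (0.29, adjusted p = 0.00457), Dlk1-Dio3 (0.22, adjusted p = 0.00457) and the hypoxia-induced list (0.17, adjusted p = 0.0306), each with adjusted p = 0.859 with an estimated correlation and 0 members past adjusted over the list alone. Among microRNAs alone the Sfmbt2 call held with the preset correlation (adjusted p = 1.05e-07, adjusted p = 0.863 with an estimated correlation), and those of miR-15/16 (adjusted p = 0.103), Dlk1-Dio3 and the hypoxia-induced list (adjusted p = 0.567 each) were lost. The last 3 calls were lost without WT normoxia number 1 (0.22, 0.00 and 0.07) or WT hypoxia number 2 (0.18, −0.046 and 0.04). The hypoxia-induced list also lost its call without KO normoxia number 1 (0.10) or KO hypoxia number 2 (0.03), miR-15/16 without KO hypoxia number 1 (0.23) and Dlk1-Dio3 without KO hypoxia number 2 (0.17). WT normoxia number 2 and WT hypoxia number 1 left out gave Dlk1-Dio3 medians of 0.38 and 0.40 and hypoxia-induced medians of 0.28 and 0.32. The lists that mark other cell types, none called, had medians of 0.74 (muscle), 0.24 (neural and melanocyte), 0.10 (epithelial) and 0.05 (haematopoietic).

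**Figure D3:**
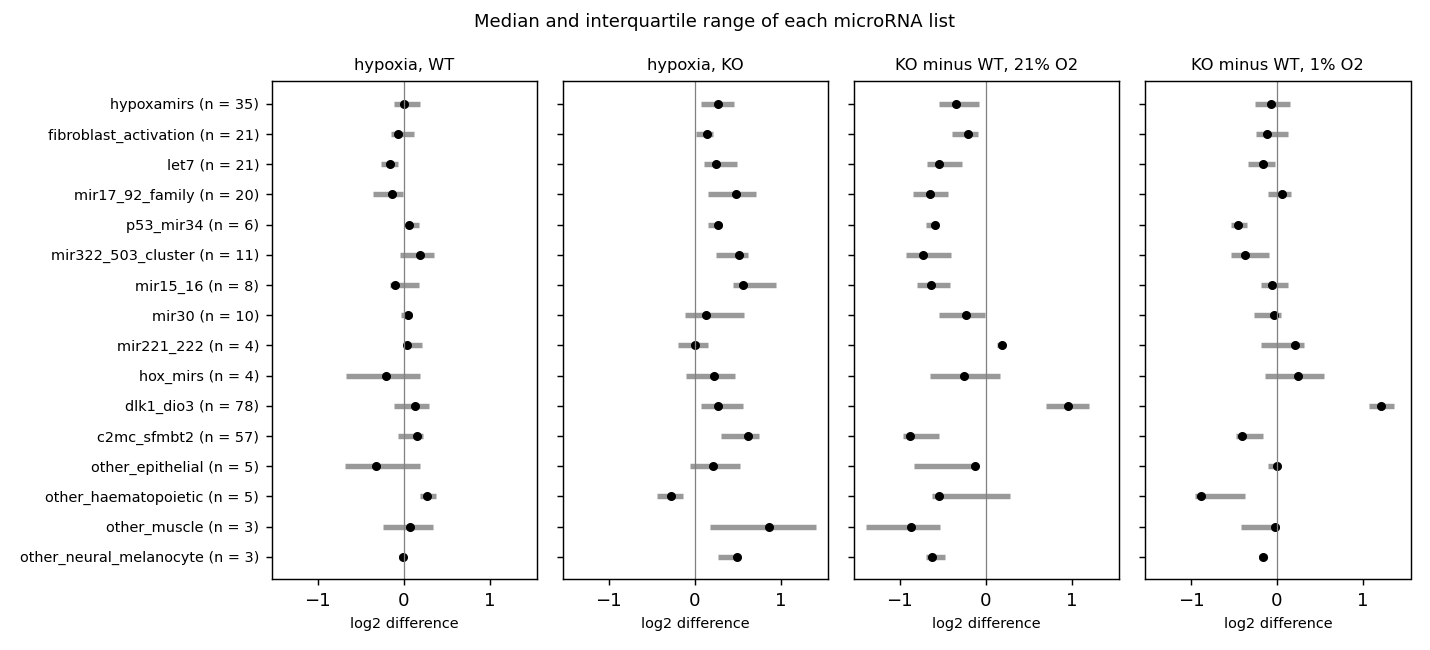
Median log2 difference (points) and interquartile range (bars) over the tested members of each of the 16 lists, in 4 comparisons: hypoxia against normoxia in WT, the same in KO, KO against WT in normoxia and KO against WT in hypoxia. The Dlk1-Dio3 list lies farthest above 0 in both genotype comparisons, at 0.96 and 1.21.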

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

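The tests of normalization, of the split by number and of cell populations for Dlk1-Dio3, and of a shift of all microRNAs and of a single library for the Sfmbt2 cluster, were chosen after the result was seen. Between the genotypes the response to hypoxia differed, by the interaction adjusted over the 2 arms, for miR-210-3p (−2.55, adjusted p = 0.00537, limma) and miR-210-5p (−4.13, adjusted p = 0.00154, limma), as it must where KO cells hold almost no miR-210. By camera with the preset correlation it also differed for 6 lists. These were the hypoxia-induced list (0.25, with 0.01 in WT and 0.27 in KO), let-7 (0.38, with −0.15 and 0.24), miR-17/92 (0.66, with −0.14 and 0.48), miR-15/16 (0.60, with −0.10 and 0.56), Dlk1-Dio3 (0.19, with 0.13 and 0.27) and the Sfmbt2 cluster (0.44, with 0.16 and 0.61). None of the 6 was called with an estimated correlation. Of 80 named features, 1, the small nuclear RNA FR231715, moved in opposite directions in every library of the 2 genotypes (−0.59 in WT, 1.64 in KO). It had been named for its small p in KO hypoxia, and with 2 libraries per group such a separation can arise by chance. The test of the difference itself, 2.22, did not pass over all features (limma, adjusted p = 0.917). With 2 libraries per group no test for an outlying library was made.

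The Dlk1-Dio3 microRNAs were higher in KO at both oxygen levels with the preset correlation, a call lost with an estimated correlation (adjusted p = 0.408 in normoxia and 0.650 in hypoxia, camera of limma). A scaling of whole libraries, which moves all microRNAs alike, is argued against. After quantile normalization the list still stood 1.26 above the other microRNAs (1.04 against −0.22). Depth was not varied, so its effect stays open. A split between number 1 and number 2 libraries is not the whole cause, since the lowest of the 4 medians within a number was 0.51 and the highest 1.61. Different cell populations stay open: between the 2 WT hypoxia libraries alone the members differed by a median of 0.94 (0.74 in WT normoxia, −0.027 in KO normoxia and 0.11 in KO hypoxia, number 2 minus number 1), beside 1.08 between the genotypes. Each genotype may come from 1 cell line. The genotype itself, and imprinting at this domain in the lines, also stay open and were not tested.

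The Sfmbt2 cluster was lower in KO normoxia with the preset correlation, a call also lost with an estimated correlation (adjusted p = 0.408). A shift of all microRNAs is argued against, since the list stood −0.68 from the other microRNAs (themselves at −0.21, adjusted p = 3.60e-11 against microRNAs alone, lost with an estimated correlation). A single library is not the whole cause, since the median was −0.50 without KO normoxia number 2 and −1.13 without KO normoxia number 1. Copies that share their first 18 bases, or have values correlated above 0.98, do not alone make up the pattern. With such copies removed, 38 members had a median of −0.74, with 36 lower. Members offset or differing by a few bases may still share reads, so shared reads stay open. The genotype or the state of the KO normoxia cells stays open as an explanation, and in hypoxia the difference was smaller (−0.41).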

How the results depend on the processing

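Scaling to the microRNA total, tests on microRNAs alone, leaving out KO normoxia number 2 and KO hypoxia number 1 together, and the reruns of lists under alternatives other than an estimated correlation and shared stems were chosen after the results were seen. The planned count model was not run, since the values are not raw counts, and leaving out a library assumes that the lone library varies like the other groups. Of 137 recomputed counts of features, 126 stayed within 1.5 times the count reported and 11 moved. The counts at an unadjusted p under 0.05 were not among these. In every contrast they changed with the library left out. Of 198 recomputed miR-210 values 189 kept direction and side of the threshold. Of 560 recomputed list calls 434 held, 120 were lost and 6 turned. In WT hypoxia the count of 0 was 1 with a pseudocount of 8 (miR-210-5p 3.15), 1 with a mean of at least 50 (3.63) and 8 with the replicate block (miR-210-3p 2.55, miR-210-5p 3.63). The numbers 1 and 2 correlated between groups in their deviations (r from 0.15 to 0.55), and with the block the genotype mean gave 91 features and the hypoxia mean 3. The genotype mean gave 16 with TMM factors and 85 on the microRNA total, against 2 as deposited, and 2 to 29 without 1 library. This scaling moved the median of all features from −0.06 to 0.17 for KO against WT in normoxia, from −0.04 to 0.11 in hypoxia and from 0.02 to −0.13 for hypoxia in KO. In normoxia KO against WT gave 2 without an intensity trend and 1 to 2 without 1 library. In KO hypoxia miR-210-3p, at 0.01, turned to −0.026 with TMM factors, −0.11 after quantile normalization and −0.14 on the microRNA total, and ran from −0.79 to 0.80 without 1 library. With an estimated correlation 0 lists were called by camera in hypoxia in KO, KO against WT in normoxia and in hypoxia, the interaction and both means. Among microRNAs alone 2 lists were called for hypoxia in KO, 5 for KO against WT in normoxia, 1 for the hypoxia mean and 2 for the genotype mean. After quantile normalization 1 was called for hypoxia in WT, and without KO normoxia number 2 and KO hypoxia number 1 the genotype mean kept 5. The fibroblast activation median in KO normoxia turned to 0.035 on the microRNA total and ran from −0.47 to 0.023 without 1 library. Over the same omissions the lists called numbered 0 to 3 (hypoxia in WT), 3 to 7 (hypoxia in KO), 5 to 10 (genotype in normoxia), 2 to 7 (genotype in hypoxia), 3 to 9 (interaction), 2 to 5 (hypoxia mean) and 5 to 9 (genotype mean). The interaction medians ran from −0.0086 to 0.55 for the hypoxia-induced list and from −0.28 to 0.66 for Dlk1-Dio3, whose hypoxia mean ran from −0.046 to 0.40. Except where fewer features or samples enter by construction, the cause was not tested. Depth limits miR-210-5p in KO, with 0 or 1 counts per library.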

Other observations

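The test of shared reads between AsnGTT copies, the tests of small nucleolar RNAs, the splits with numbers in balance and the permutation of list medians were chosen after the result was seen. The 13 genomic asparagine AsnGTT transfer RNA features had a median log2 difference of 1.22 between WT hypoxia and normoxia, each at an unadjusted p under 0.05 and none past the threshold over all features (limma), and 0.18 in KO. A shift of all transfer RNA features is argued against, since the other 400 had a median of 0.064, although the 7 PheGAA features lay as far the other way (−1.35 in WT and 0.08 in KO, 0 at an unadjusted p under 0.05 in WT, limma). Of the pairs of copies, 24.4% correlated above 0.98 (median r 0.964). This cannot decide on reads shared between copies, since copies that share most of their reads may also fall below 0.98. How reads matching several copies were counted is not given, so the copies may not be separate measurements.

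The genotype split of the 8 libraries gave 19 features in a plain limma fit of 2 groups, and 2 of the 35 splits of 4 against 4 gave as many, so over these splits chance is not excluded. The other was number 1 against number 2, with 28, which follows a structure of the libraries by number, and with the number as a block the genotype gave 91. Of the 18 splits with 2 libraries of each number on each side, 1 gave as many, the genotype split itself (19, highest other 10), and 18 splits are too few for a share under 0.05. The oxygen split gave 0 in that fit (limma, 55 at an unadjusted p under 0.05 in the fit of 4 groups), so 35 of 35 splits must reach it (highest other 28), and the count decides nothing about chance. By exact permutation of list medians over 4 KO against 4 WT libraries, Dlk1-Dio3 stood at 6.88 against 6.03 and the Sfmbt2 cluster at 6.16 against 6.81, each with p = 0.0286, the smallest the test can give, and adjusted p = 0.229 over 16 lists.

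The small nucleolar RNAs that the file places among the Dlk1-Dio3 microRNAs were also higher in KO. The 13 tested had a median of 1.31, against −0.11 for small nucleolar RNAs elsewhere, a difference of 1.42, and 12 of 13 passed adjusted over these alone and 0 over all features (limma). The 12 are not separate measurements, since FR310934 and FR325285 overlap and match AF357341, and FR014374 and FR280892 overlap and match Gm26922. Together with the microRNAs this may reflect a difference of the whole locus between the cells of the 2 genotypes, and not of its microRNAs alone. miR-345-5p (−0.21) and miR-345-3p (−0.60), on the same chromosome outside the locus, were not higher.

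Over the microRNAs the first principal component (39.3%) parted the genotypes, the second (26.6%) number 1 from number 2, and the third KO normoxia number 2 from the rest. The 2 miR-210 arms were among these microRNAs, and how far they alone part the genotypes was not tested. Among 1451 features with a mean of at least 10, 33 equalled another in every library within 1, and 25 of these were transfer RNAs.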
